A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

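RNA of fission yeast (Schizosaccharomyces pombe) was measured on 4 two-colour oligonucleotide tiling arrays, each holding cDNA of a mutant beside cDNA of wild-type cells. Per the labels, 2 arrays compared cells lacking cbp1, which encodes a homolog of the centromere-binding protein CENP-B, with wild type at 30 °C. The other 2 arrays compared clr3 deletion clr6-1 cells, mutated in 2 histone deacetylases, with wild type at 26 °C. Cultures in rich medium (YEA) grew for 18 h to an A595 of about 0.5, and 10 mL were harvested, per the labels' protocols. From 20 µg of total RNA, cDNA was primed with anchored oligo-dT and labelled with Alexa dyes, per the labels' protocols. The series text calls the arrays of a mutant biological duplicates.

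The direction of each ratio was taken from the labels of each sample, which put the mutant in Alexa Fluor 647 (red) and the wild type in Alexa Fluor 555 (green) on all 4 arrays. The text on the series as a whole gives the dyes the other way round. The labels of the samples and the labelling protocol were followed, and under the series text every sign reported here would turn. The brighter and dimmer strands, the groups of wild-type brightness and the notes on channels near background take green as wild type, and would then rest on the mutant. No dye was swapped, so a dye effect of a probe stays in every ratio of both mutants. The file headers place the 2 arrays of a mutant on a slide and scan of their own. Slide, scan, growth temperature and mutant therefore cannot be told apart. Each array carries its own wild-type RNA, and no control array was shared between the mutants.

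The scanner files hold spot intensities extracted with Agilent Feature Extraction 10.5.1.1, per the file headers and the submitters' processing notes. The mean pixel intensity of each spot and the median intensity of its local background were used as deposited, without subtraction by the authors. The processed intensities and the log10 ratio of red over green in the same files were, per the file headers, background-subtracted, detrended and dye-normalized by the scanner software. Other columns used are 0 or 1 flags for signal above background, saturation and outlier spots, per the file headers. A deposited table of log2 ratios gives the authors' processed values of the same arrays, for which the submitters' processing notes name limma 3.10.2. Set against the ratios computed here, its columns correlated at 0.995, 0.995, 0.995 and 0.995 with slopes of 1.07, 1.05, 0.887 and 0.893, and their medians were 0.00, -0.01, 0.00 and 0.00. Its direction is therefore mutant over wild type under the dyes of the labels, on a log2 scale, while its background correction and centring are not given in the sources used here.

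Each array holds 42968 spots, of which 41551 are tiles and 1417 are controls. Tiles are 60 bases long and lie every 300 bp on alternating strands, so that neighbours on the same strand are 600 bp apart. A tile was identified by the contig, position and strand mark in its name. Tiles with and without an R in the name read opposite strands, and which transcripts each of the 2 sets reads was not settled. The genome build of these positions is not given in the sources used here. No reference genome was used, and the files do not pair tiles with genes. No tile was therefore assigned to a gene, centromere, telomere or transposon, and contigs are called by the names in the files (chromosomes 1 to 3, mat, mito and pNSU).

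Background was corrected with normexp (offset 50) and arrays were normalized by loess, with control spots and outlier spots at weight 0, in limma 3.58.1 under R 4.3.3. Outlier spots were left out, and of the tiles 41119 were kept as well above background in either channel on both arrays of at least 1 mutant. A linear model (lmFit, eBayes) over all 4 arrays tested the mean log2 ratio of each mutant against 0 and the difference between the mutants. A tile was tested for a mutant where both arrays of that mutant had a value, and for the difference where all 4 had. Every adjusted p comes from limma with the Benjamini-Hochberg method, and tiles under 0.05 were called. All 4 arrays share 1 estimate of the spread because 2 arrays per mutant leave few degrees of freedom, and the number of arrays limits the precision. Where a channel was not well above background on both arrays of a mutant, the fitted ratio is not exact, and a bound was computed apart from it. Folds of runs average the fitted ratios and are not bounds. The bound sets the bright channel's mean over both arrays against the dim channel's mean of, per array, the higher of the spot's own signal and the lowest signal well above background (after loess and Aquantile), and it is open to dye bias.

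A run is a series of at least 2 neighbouring tiles of the same strand, at most 1200 bp apart, that were all called in the same direction with the same sign on both arrays. The runs described by position are the 6 with the largest mean log2 ratio in each direction for each comparison, outside the repeat families. Runs in which every tile shares sequence with a distant tile were left out, but a run may hold some such tiles. This rule adapts, after the files were seen, one written for genes. Longest runs are given in addition. Neighbouring tiles can read the same transcript and are not independent.

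Repeat families were built from the probe sequences alone. The 934 tiles that share 25 bases with a tile at least 1000 bp away were joined into 67 blocks of at least 3 tiles with gaps of at most 2000 bp. Blocks were linked where they shared at least 3 sequences, and the 4 groups with at least 4 blocks were kept as families. Such probes cannot tell copies apart, so a block's value can hold signal from its relatives. In each family the strand with the brighter wild-type channel is called the brighter strand, and the mean ratio of each strand was fitted beside the tiles. Outside the families, a tile was called brighter-strand or dimmer-strand where its wild-type brightness lay at least 4-fold above or below that of its opposite-strand neighbours, judged on the arrays of the other mutant. Families and strand classes were defined after the files were seen.

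Classes of tiles (within 100 kb of chromosome ends, contigs, strand classes and families) were compared with all other tiles by camera in limma, with a preset correlation of 0.01 and, as an alternative, an estimated correlation. The groups, ratio direction, background correction, normalization, filter, linear model, threshold and all but 2 of the alternatives were fixed before the data were examined. The use of single tiles in place of genes, the runs, the families and the strand classes were set after values had been seen. On simulated ratios for 29281 tiles, all 100 tiles changed by log2 1 and all 100 changed by log2 2 were called in each of the 3 comparisons, with 25, 17 and 22 unchanged tiles called for cbp1 deletion, clr3 deletion clr6-1 and the difference. The simulated noise was independent between tiles and held no dye bias. These changes were large beside the spread, so calling them was nearly certain, and the simulation checks only that the fit runs as meant.

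Alternatives were no background correction, the scanner software's own ratios, the deposited table, median centring in place of loess, no filter on dim spots, a filter for signal in both channels on all arrays, an intensity trend in eBayes, each mutant's own arrays, the replicate number as a block, and leaving out each array. Outlier spots kept, and tiles with shared sequence or a name suffix left out, were added after the files were seen. Planned analyses by gene were left out for want of a pairing of tiles with genes: sense and antisense values, gene lists, the targeted genes cbp1, clr3 and clr6, retrotransposons by name, the summary of probes per gene and probes with several genome matches. The 2 strands were compared tile by tile in place of sense and antisense genes.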

Results

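Transcripts of both DNA strands were measured across the fission yeast genome in 2 mutants, each hybridised against wild-type cells, with 2 arrays per mutant. Cbp1 is a DNA-binding homolog of the mammalian centromere protein CENP-B, and the study concerns its part, with the histone methyltransferase Set1, in silencing retrotransposons. Clr3 and Clr6 are histone deacetylases that act in transcriptional silencing. The median red signal, that of the mutant, was 989 and 1262 on the cbp1 deletion arrays and 702 and 752 on the clr3 deletion clr6-1 arrays. The median green signal, that of the wild type, was 899 and 984 against 330 and 349. Between 89.8% and 99.1% of tiles were well above background in red and between 82.0% and 98.2% in green, and no tile was saturated. Outlier marks removed 11.5% and 15.0% of spots on the cbp1 deletion arrays and 14.2% and 12.3% on the others. On the clr3 deletion clr6-1 arrays they removed 63.4% and 55.3% of the brightest 1 of 10 equal groups of tiles, so strongly expressed sequences are thinly covered there.

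Across tiles, which are not independent replicates, log2 ratios correlated at 0.932 between the cbp1 deletion arrays and at 0.979 between the clr3 deletion clr6-1 arrays. Between arrays of different mutants the correlation was 0.274 to 0.311. The median absolute difference between the arrays of a mutant was 0.13 and 0.11 on the log2 scale. All signs are mutant over wild type by the dyes on the sample labels, and would turn under the dyes in the text of the series, so that rises here would read as falls. Temperature, slide and scan were the same for both arrays of a mutant and differed between the mutants, so that they cannot be told apart from the mutants in any comparison between them. The deleted genes were not looked up, since no source used here pairs tiles with genes, and the strain labels have no check of that kind.

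Sequences present in several copies formed 4 families. Family 1 comprised 10 blocks lying in 1 area on each chromosome, at 3753600 to 3785700 on chromosome 1, 1599600 to 1647600 on chromosome 2 and 1070100 to 1141200 on chromosome 3. Family 2 comprised 9 separate blocks spanning 1800 to 4500 bp, with 7 on chromosome 1, 1 on chromosome 2 and 1 on chromosome 3. Family 3 comprised 8 blocks, 6 on chromosome 1 and 2 on chromosome 2, all near the chromosome ends. Family 4 comprised 7 short blocks, 6 on chromosome 3 and 1 on chromosome 1.

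The first comparison asked which sequences change when Cbp1 is absent. The dispersed family 2 rose most among the families. Its brighter strand was 8.22-fold higher in cbp1 deletion cells (log2 3.04, SE 0.0844, 2 arrays) and its dimmer strand 2.40-fold higher (log2 1.27, SE 0.0830). Every measured tile of both strands rose, 35 of 35 on the brighter and 39 of 39 on the dimmer. Family 3, at the ends of chromosomes 1 and 2, fell on both strands, and several regions outside the families rose more than 10-fold.

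The rise of family 2 had an adjusted p of 1.64e-09 on the brighter strand and 6.94e-07 on the dimmer strand, in both cases above 0 on both arrays. Block by block, the brighter strand lay between log2 2.77 and 3.45 and the dimmer strand between 0.53 and 1.56 in the 9 blocks. Family 3 changed by log2 -0.85 (SE 0.0829, adjusted p = 1.40e-05) on the brighter strand and by -1.08 (SE 0.0832, adjusted p = 2.37e-06) on the dimmer strand. Of its dimmer-strand tiles 80 of 92 fell and 5 rose, and of its brighter-strand tiles 60 of 88 fell and 12 rose, with 1 of 8 blocks above 0 (0.16). The brighter strand stood at -1.55 among tiles above background in both channels on all arrays. Family 4 rose by 0.70 (adjusted p = 6.36e-05) and 0.38 (adjusted p = 0.00305), the second with an adjusted p of 0.0505 in the scanner software's own ratios. Family 1 rose by 0.38 on each strand (adjusted p = 0.00336 and 0.00355), with single tiles going both ways. When compared with all other tiles, all 8 family strands stood apart with the preset correlation, but with an estimated correlation adjusted p = 0.116 to 0.416 and none passed. The latter test rests on the few degrees of freedom of 4 arrays and cannot show that a family did not shift.

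**Figure D1:**
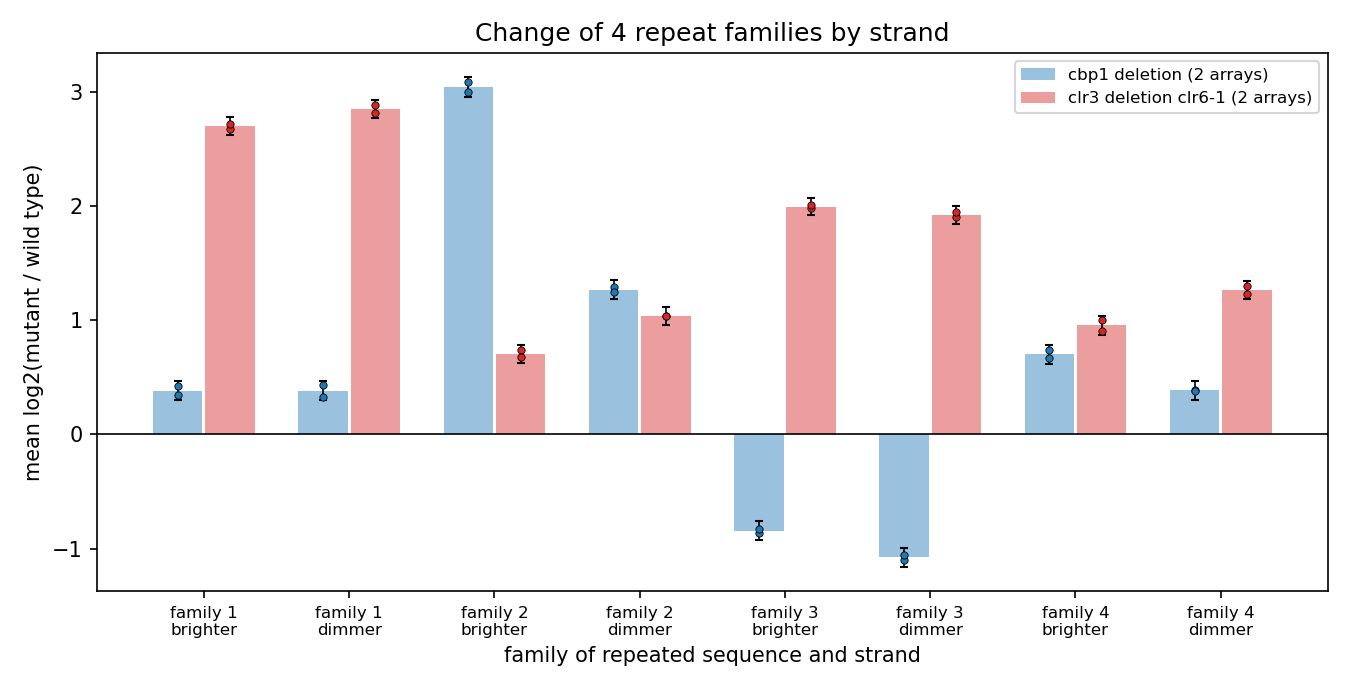
Mean log2 ratio of mutant over wild type for the brighter and dimmer strand of 4 repeat families in cbp1 deletion and clr3 deletion clr6-1 cells, where bars are means, points are the 2 arrays and error bars are 1 standard error. Family 2 stood at 3.04 on its brighter strand in cbp1 deletion cells and 0.71 in clr3 deletion clr6-1 cells (0.0850 there under median centring), and family 3 lay below 0 in the former and near 2 in the latter.

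The ends of chromosomes 1 and 2 were divided in cbp1 deletion cells. In the outermost 20 kb the median log2 ratio lay between -1.15 (chromosome 1, right) and -0.36 (chromosome 2, right), with 152 tiles down and 11 up over the 4 ends. Blocks of family 3 lie in all of these stretches, for example from 600 to 16500 and from 4494300 to 4510500 on chromosome 2. The fall there therefore repeats, at least in part, that of family 3, and the 4 ends are not separate observations. Further in, a stretch of chromosome 1 from 5491800 to 5529600 rose as a run of 51 measured tiles (mean log2 1.44, 2.71-fold), with 49 of 58 tiles of the opposite strand also up. The wild-type channel was not well above background on 15 of the 51 tiles, where the rise was at least 1.14-fold to 32.6-fold. On chromosome 2 a run of 15 tiles of the R strand from 57000 to 65400 rose 7.39-fold (log2 2.89). The wild-type channel was not well above background on 2 of them, where the rise was at least 1.15-fold and 1.90-fold. This run was followed, on the strand without an R, by a fall of 3.68-fold over 19 tiles from 91200 to 103800 (log2 -1.88). Of those 19 tiles, 11 share sequence with tiles elsewhere, so the fall may lie in part at other copies. The outermost 20 kb of chromosome 3 rose, by a median of 0.62 at the left end and 0.93 at the right.

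Taken over 100 kb, the ends of chromosomes 1 and 2 held 406 tiles that rose and 409 that fell, with a median log2 ratio of 0.04 over 931 tiles. The class did not stand apart from other tiles (adjusted p = 0.994, with the test's direction down). With tiles above background in both channels on all arrays, its median was -0.43 (adjusted p = 1.30e-06), and without tiles of shared sequence or a name suffix it was 0.24 (adjusted p = 0.000247), so that its direction was not settled. The ends of chromosome 3 rose by a median of 0.11 (adjusted p = 0.0249, but adjusted p = 0.475 with an estimated correlation), a call lost under median centring (0.12, adjusted p = 0.0619) and without cbp1 deletion replicate 2 (0.08, adjusted p = 0.0604). Without tiles of shared sequence or a name suffix the median there was 0.00 over 323 tiles (adjusted p = 0.825).

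**Figure D2:**
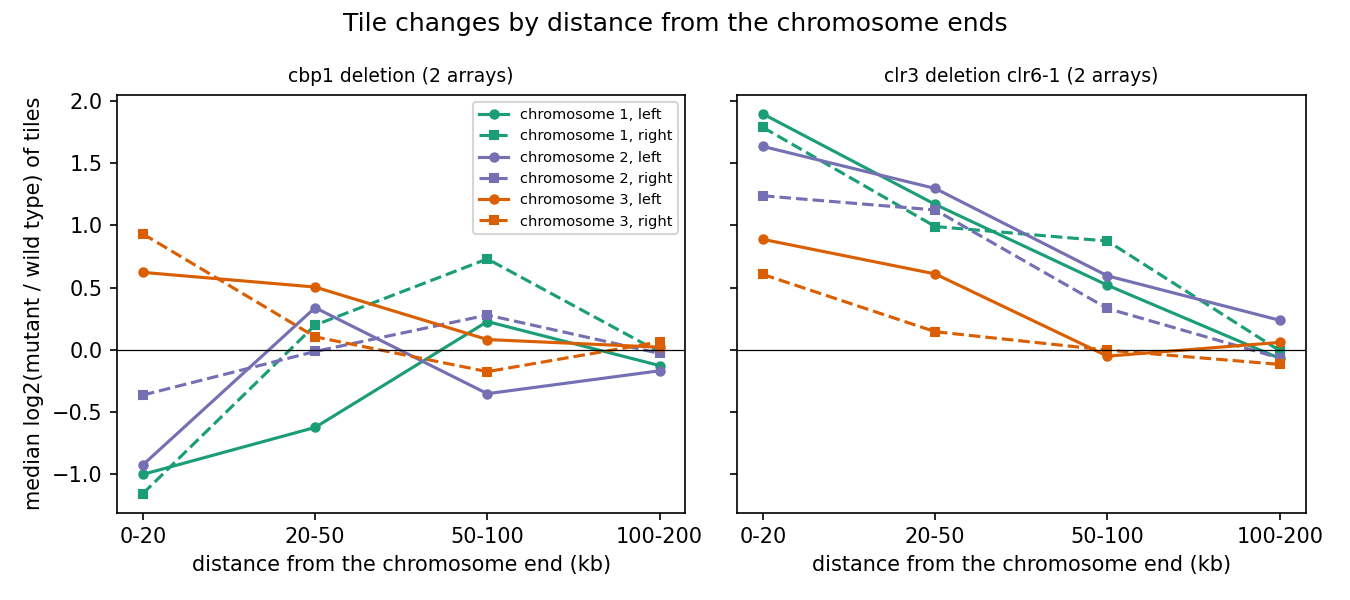
Median log2 ratio of mutant over wild type of tiles by distance from the chromosome end in kb, with 1 line per end and 1 panel per mutant. In cbp1 deletion cells the outermost 20 kb lay at -1.15 to -0.36 on chromosomes 1 and 2 and at 0.62 and 0.93 on chromosome 3, and in clr3 deletion clr6-1 cells all 6 ends lay between 0.61 and 1.89.

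Outside the families, the largest rises by run were short regions of 3 to 6 tiles. The region from 2985600 to 2986800 on chromosome 1 rose 72.4-fold (mean log2 6.18, SD 0.0988 between 2 arrays). It was followed by 2043000 to 2045400 on chromosome 3 (27.7-fold) and 1950000 to 1952400 on chromosome 2 (25.6-fold). In the former the wild-type channel was not well above background on 1 of 5 tiles, where the rise was at least 2.22-fold. Regions from 3160800 and 4522800 on chromosome 1 rose 15.1-fold and 13.6-fold, and 1 of 5 tiles of the second shares sequence with a tile elsewhere. The region from 4411800 to 4415400 on chromosome 2 rose 12.5-fold on average (log2 3.65, and more than 1.5 times that over its tiles above background in both channels on all arrays), and within it the tile chr2_14716_4414800 rose 340-fold (log2 8.41, SE 0.0916, adjusted p = 3.02e-11). The largest falls by run were smaller. They were 7.35-fold at 4459800 to 4460400, 6.75-fold at 2870100 to 2870700 and 6.14-fold at 466500 to 467700 on chromosome 2, and 6.25-fold at 5445300 to 5446500 on chromosome 1. At 3512700 to 3513900 on chromosome 2 the R strand fell 5.21-fold while the opposite strand had a mean log2 ratio of 2.32. A fall of 5.04-fold lay at 2327100 to 2328300 on the same chromosome. Among tiles without shared sequence or a suffix in the name, chr1_2724_817200 fell most (log2 -4.16, SE 0.0827, adjusted p = 1.77e-10).

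Of 33653 tiles tested in cbp1 deletion cells, 8781 rose and 8804 fell (limma, adjusted p under 0.05, median SE 0.0897). At least 2-fold changes were fewer, 1456 up and 840 down, and at least 4-fold changes numbered 351 and 131. The tiles called fell to 9896 with the scanner software's own ratios. The balance of rises and falls moved with the setting, to 12261 and 9883 with outlier spots kept and to 8741 and 10717 with the deposited table. Tiles of contig mito rose by a median of 0.46 (40 up, 0 down, 18 not called) and those of the pNSU contigs by 0.49 (71 up, 10 down). For mito, adjusted p = 3.03e-08 with the preset correlation and adjusted p = 0.475 with an estimated correlation, and the median was 0.26 without cbp1 deletion replicate 2 and under median centring. For pNSU they were adjusted p = 3.66e-11 and adjusted p = 0.261 with an estimated correlation. The pNSU contigs could not be tested without tiles of shared sequence or a name suffix.

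The second comparison asked which sequences change when Clr3 is absent and Clr6 is mutated, at 26 °C. Family 1 rose on both strands, 6.49-fold on the brighter (log2 2.70, SE 0.0786, 2 arrays) and 7.21-fold on the dimmer (log2 2.85, SE 0.0802). Family 3 rose 3.98-fold (log2 1.99, SE 0.0774) and 3.79-fold (log2 1.92, SE 0.0778). Tiles of contig mat and of the ends of chromosomes 1 and 2 had medians of 0.82 and 0.92, which passed with the preset correlation but not with an estimated one (adjusted p = 0.0696 for both with an estimated correlation). Family 2 rose 2.05-fold on the dimmer strand (log2 1.04, SE 0.0774), while its brighter strand stood at 0.71 and, under median centring, at 0.0850.

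The adjusted p was 6.11e-08 and 5.10e-08 for the strands of family 1 and 2.60e-07 and 3.16e-07 for those of family 3. In family 1 the 10 blocks lay between log2 0.08 and 7.09 on the brighter strand and between -0.11 and 6.10, with 9 above 0, on the dimmer, and in family 3 all 8 blocks lay above 0 on both strands. For family 2 the adjusted p was 8.69e-06 on the dimmer strand, where 38 of 42 tiles rose, and the value was 0.60 under median centring. On the brighter strand it was 8.98e-05 over 11 tiles left after outlier marks, and 0.359 under median centring. Family 4 rose by 0.95 (adjusted p = 1.63e-05; 1.60 with outlier spots kept) and 1.26 (adjusted p = 3.00e-06). Among tiles above background in both channels on all arrays the brighter strands of families 1 and 3 stood at 4.06 and 3.03, and that of family 3 at 3.06 with the scanner software's ratios. All 8 family strands stood apart from other tiles with the preset correlation, and with an estimated correlation adjusted p = 0.0696 to 0.359 and none passed. As in the first comparison, the few degrees of freedom of the latter test left little room to pass.

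At the chromosome ends the rise was steepest in the outermost 20 kb, with medians of 1.89 and 1.79 on chromosome 1, 1.63 and 1.24 on chromosome 2, and 0.89 and 0.61 on chromosome 3. On chromosomes 1 and 2 these stretches hold blocks of family 3, so the rise there repeats, at least in part, that of the family. Between 100 and 200 kb the medians lay between -0.12 and 0.24. Within 100 kb of the ends of chromosomes 1 and 2, 801 of 1027 tiles rose and 65 fell. The median log2 ratio was 0.92 over 931 tiles (adjusted p = 5.69e-22, but adjusted p = 0.0696 with an estimated correlation). Without tiles of shared sequence or a name suffix it was 0.78 over 660 tiles. With the scanner software's ratios the medians of these ends, of contig mat and of pNSU were 1.82, 1.47 and 2.13. For the ends of chromosome 3 the median was 0.20 (adjusted p = 0.0262, adjusted p = 0.429 with an estimated correlation), and the call was lost under median centring (0.20, adjusted p = 0.105) and without tiles of shared sequence or a name suffix (0.02, adjusted p = 0.605). The longest run, 33 tiles from 5550000 to 5573400 on chromosome 1, rose 5.39-fold (log2 2.43), while the same tiles had a mean of -1.21 in cbp1 deletion cells. In it the wild-type channel was not well above background on 9 tiles. This run overlaps blocks of family 3, and 14 of its tiles share sequence with tiles elsewhere, so it largely repeats the change of that family.

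Contig mat had a median of 0.82 over 82 tiles with values on all 4 arrays (adjusted p = 1.76e-07, adjusted p = 0.0696 with an estimated correlation). Of its 101 tiles tested in clr3 deletion clr6-1 cells, 64 rose and 15 fell. On the arrays of this mutant alone its median was 0.62. Its median was 0.50 without background correction, 0.52 among tiles above background in both channels on all arrays, and 1.58 without tiles of shared sequence or a name suffix. On that contig the tile mat_106_31800_R rose 195-fold (log2 7.61, SE 0.0810, adjusted p = 1.31e-09). The pNSU contigs rose by a median of 1.16 over 102 tiles (101 up, 6 down of 125 tested), with adjusted p = 2.59e-14 and adjusted p = 0.154 with an estimated correlation. They could not be tested without tiles of shared sequence or a name suffix, so their signal may come from copies elsewhere. Contig mito had a median of 0.61 (adjusted p = 4.34e-06, adjusted p = 0.490 with an estimated correlation), which median centring turned to -0.04.

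**Figure D3:**
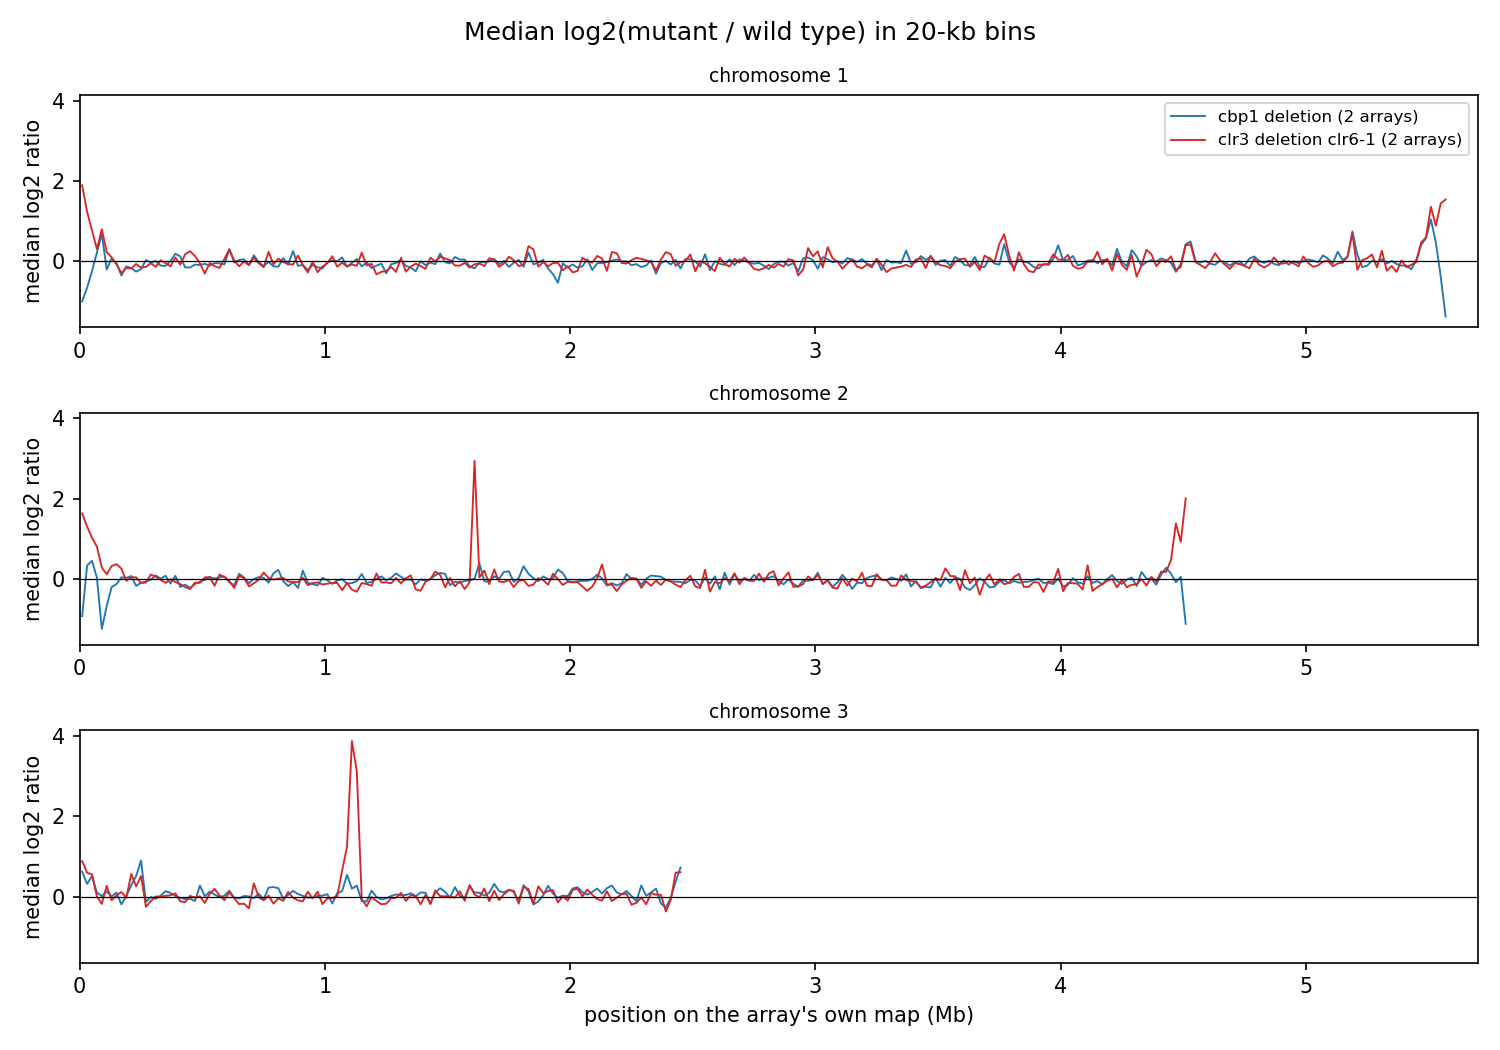
Median log2 ratio of mutant over wild type in bins of 20 kb along chromosomes 1, 2 and 3, with position in Mb on the array's own map and 1 line per mutant (2 arrays each). The peaks of clr3 deletion clr6-1 cells in the bins from 1600 kb on chromosome 2 and 1100 kb on chromosome 3 lie in the areas of family 1, and at the ends of chromosomes 1 and 2 the lines of the mutants part.

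Among regions outside the families, the one from 3160800 to 3161400 on chromosome 1 rose 51.2-fold (mean log2 5.68, SD 0.0628 between 2 arrays). Both strands rose between blocks of family 1 on chromosome 2, by 42.3-fold at 1615800 to 1617000 and by 19.5-fold on the R strand at 1614900 to 1617300. The wild-type channel was not well above background on 1 of 2 and 2 of 4 of these tiles, for which the bounds were at least 38.3-fold, and at least 12.1-fold and 41.6-fold. Near the left end of chromosome 3, runs at 13500 to 15900 and 3300 to 5100 rose 41.1-fold and 26.0-fold. Of their tiles, 2 of 3 and 2 of 4 share sequence with tiles elsewhere, as do 2 of 4 in the R-strand run at 1614900. The signal of these 3 runs may therefore come in part from other copies. The tiles at 2986800 and 2987400 on chromosome 1 rose 25.6-fold. The largest fall covered 255900 to 257700 on chromosome 2, where the mutant channel was not well above background on 2 of 3 tiles and the falls were at least 44.2-fold and 57.8-fold. There the tile chr2_857_257100 had an adjusted p of 6.19e-08. The next falls were 4.32-fold at 2939100 to 2940300 and 3.88-fold at 2935500 to 2937300 on chromosome 1, and 4.17-fold at 359700 to 360300 and 4.11-fold at 2273100 to 2273700 on chromosome 2. A fall of 3.69-fold lay at 1433700 to 1434300 on chromosome 1.

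Of 34510 tiles tested, 12078 rose and 11863 fell (limma, median SE 0.0865). The balance turned with the scanner software's ratios, 10484 up and 13057 down, and among tiles above background in both channels on all arrays, 8508 up and 10495 down. Large changes were mostly rises, 4074 against 1681 at 2-fold and 1196 against 77 at 4-fold. The wild-type channel alone was not well above background on 2667 tiles and the mutant channel alone on 293, for which fitted ratios are no bound. The filter kept tiles bright in either channel, so the former can add to the large rises. The balance at 2-fold and 4-fold was not counted among tiles above background in both channels. With the scanner software's ratios the median of all tiles moved from -0.01 to -0.12.

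The difference between the mutants was tested directly on 29281 tiles with values on all 4 arrays. The brighter strand of family 2 was higher in cbp1 deletion cells by 5.92-fold (log2 2.56, SE 0.129), whereas families 1 and 3 were lower there than in clr3 deletion clr6-1 cells. The dimmer strand of family 2 differed by 0.22 (SE 0.116). Contigs mat and pNSU and the ends of chromosomes 1 and 2 had medians below 0, called with the preset correlation only (adjusted p = 0.103, 0.235 and 0.0895 with an estimated correlation).

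For family 2 the adjusted p was 4.56e-07 on the brighter strand, where all 10 tiles with values on all arrays were higher, and 0.135 on the dimmer strand. The dimmer-strand difference was called under median centring (0.73, adjusted p = 0.000332), without background correction (0.29) and with the scanner software's ratios (0.50). Family 1 differed by -2.57 and -2.48 (adjusted p = 2.62e-07 and 3.44e-07) and family 3 by -2.52 and -3.07 (adjusted p = 2.75e-07 and 8.06e-08). The brighter-strand difference of family 3 was -4.46 among tiles above background in both channels on all arrays and -3.84 with the scanner software's ratios. Family 4 differed by -0.88 on the dimmer strand (adjusted p = 0.000186) and by -0.14 on the brighter (adjusted p = 0.328), where keeping outlier spots gave -0.80 (adjusted p = 0.000359) and the other settings gave -0.38 to -0.08. The ends of chromosomes 1 and 2 differed by a median of -0.88 (adjusted p = 6.16e-16, adjusted p = 0.0895 with an estimated correlation), contig mat by -0.53 (adjusted p = 2.19e-05, adjusted p = 0.103 with an estimated correlation) and pNSU by -0.66 (adjusted p = 4.29e-08, adjusted p = 0.235 with an estimated correlation). With the scanner software's ratios the ends and pNSU differed by -1.74 and -1.50, and without background correction by -0.58 and -0.30. Without tiles of shared sequence or a name suffix contig mat differed by -1.17, and pNSU could not be tested. For contig mito the median was -0.10 (adjusted p = 0.583), and its direction was not settled, at -0.29 without cbp1 deletion replicate 2 (adjusted p = 0.0371) and 0.36 under median centring (adjusted p = 0.00629).

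By run, the largest differences towards cbp1 deletion were 6.72-fold at 2977200 to 2978400 and 6.69-fold at 107700 to 108300 on chromosome 1, and 6.21-fold at 1208100 to 1208700 on chromosome 3. Others of 5.22-fold at 2044200 on chromosome 3 and of 5.17-fold at 4415100 and 5.06-fold at 61500 on chromosome 2 followed. Towards clr3 deletion clr6-1 they were larger, 37.6-fold at 1615800 and 27.2-fold at 2131500 on chromosome 2. They continued with 22.2-fold at 1618800 and 20.7-fold at 4459800 on chromosome 2, 16.2-fold at 2205000 on chromosome 3 and 15.8-fold at 5550000 on chromosome 1. Of the tiles at 1208100, 61500 and 2131500, 1 in each run shares sequence with a tile elsewhere. In clr3 deletion clr6-1 cells the wild-type channel was not well above background on 1 of 2 tiles at 1615800, 1618800 and 4415100, 2 of 3 at 61500 and 3 of 4 at 5550000. In cbp1 deletion cells it was so on 1 tile each at 4415100, 61500 and 5550000, and the mutant channel on 1 at 5550000, so the folds at these 5 places are not exact. At 5550000 the log2 difference of -3.98 came to -6.02 over tiles above background in both channels on all arrays. At 4459800 the mutants went opposite ways, with means of -2.88 in cbp1 deletion and 1.49 in clr3 deletion clr6-1 cells. In all, 8391 tiles were higher and 9011 lower in cbp1 deletion cells, 1877 and 3632 by at least 2-fold. That balance of all called tiles turned with the scanner software's ratios, 8334 and 7810, and among tiles above background in both channels on all arrays, 6942 and 6398.

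Tiles changed in the same direction in both mutants more often than independent lists give. Those that rose in both numbered 3846, against 2836 for independent lists, and 3818 fell in both, against 2602. At 2-fold or more, 524 rose in both against 157 for independent lists, and 134 fell in both against 34.9. Tiles going opposite ways were fewer than independent lists give, 1630 against 2652 and 2020 against 2783. At 2-fold or more, however, 154 tiles fell in cbp1 deletion and rose in clr3 deletion clr6-1 cells, against 89.2, while 12 went the other way, against 61.3. Family 3 can hold part of the 154. On its brighter and dimmer strands 34 and 49 tiles fell at least 2-fold in cbp1 deletion cells, and 1 and 1 rose. In clr3 deletion clr6-1 cells 55 and 71 rose at least 2-fold, and 0 and 0 fell. The overlap outside the families was not counted. The correlation of the mutants' mean log2 ratios across 29281 tiles was 0.265 (Spearman's rho 0.261), and tiles are not independent replicates. Overlapping runs at 2986800 and at 3160800 on chromosome 1 were among the largest rises in each mutant. The run from 5491800 to 5529600 averaged 1.44 in cbp1 deletion and 1.43 in clr3 deletion clr6-1 cells.

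The study's title names silencing in both directions, and the strands were therefore compared between neighbouring tiles. In cbp1 deletion cells 286 of 26495 opposite-strand neighbours both rose at least 2-fold, against 50.2 for independent strands. In clr3 deletion clr6-1 cells 539 of 27280 did, against 365. Neighbours that both fell at least 2-fold numbered 139 against 16.8 in the former and 140 against 78.2 in the latter. Neighbours that went opposite ways by that much numbered 69 against 58.2 in cbp1 deletion and 405 against 338 in clr3 deletion clr6-1 cells. Across neighbours on opposite strands the log2 ratios correlated at 0.280 in cbp1 deletion and 0.109 in clr3 deletion clr6-1 cells, while neighbours on the same strand correlated at 0.500 and 0.486. Copying of 1 strand into second-strand cDNA would also make opposite strands change together, and it was not tested for these pairs. In clr3 deletion clr6-1 cells the dimmer-strand tiles, family tiles included, had a median of 0.08 over 13810 tiles. Of 15076 tested, 6149 rose and 4111 fell. The brighter-strand tiles had a median of -0.12 over 6272 tiles, with 2160 up and 3947 down of 9012 tested. With the preset correlation adjusted p = 0.0124 and 0.00443, and with an estimated correlation adjusted p = 0.0952 for both. The brighter-strand call was also lost among tiles above background in both channels on all arrays (adjusted p = 0.0708), though the median stayed at -0.12. In cbp1 deletion cells the medians were -0.03 and -0.01, with adjusted p = 0.382 and 0.767. Under median centring they were 0.10 and -0.19 and both were called (adjusted p = 0.00817 and 8.52e-11), and those of clr3 deletion clr6-1 cells were 0.32 and -0.60, so the size of this shift, and in cbp1 deletion cells its direction, depended on the normalization.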

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

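The settings that kept outlier spots and that left out tiles with shared sequence or a name suffix were chosen only after the results were seen, and the others were planned. No result changed sign under any setting among the counts, fitted families and runs recomputed. Of the values that answer a comparison, 108 counts stayed within 1.5 times and 78 values of family 2 kept their direction and call, 1 of them moving by more than 1.5 times (its dimmer strand in clr3 deletion clr6-1 cells, to 0.60 under median centring). The other changes follow, and their cause was not tested unless given. The scanner software's ratios called 9896 tiles in cbp1 deletion cells and left 2237 tiles up in both mutants and 2539 down in both. Keeping outlier spots tested 41119 tiles and gave 5991 up in both, more tiles being tested. With an estimated correlation 0 of the 12, 15 and 11 region classes called for cbp1 deletion, clr3 deletion clr6-1 and the difference passed. That test has few degrees of freedom here, so this count does not show that the shifts were absent. Without tiles of shared sequence only 7 classes could be tested, and 3, 5 and 4 passed; family 1 kept 4 brighter-strand tiles there, lost its calls and had class medians of 0.05, -0.03 (2.82 with all tiles) and 0.08 (-2.86). Family 2 on its brighter strand in clr3 deletion clr6-1 cells came to 0.0850 under median centring. Its dimmer-strand difference between the mutants passed at 0.29 without background correction, 0.50 with the scanner software's ratios and 0.73 under median centring. Median centring turned the class medians of contig mito and of that brighter strand in clr3 deletion clr6-1 cells to -0.04 and -0.09, and called 921 tiles of clr3 deletion clr6-1 in the opposite direction.

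Of the values of other families 244 kept their direction and call, 12 of them moving by more than 1.5 times, while 1 gained a call and 1 lost it. Of those of single runs 398 moved by no more than the spread between arrays (for differences, the median SE) and 120 by more, in the same direction. Leaving out each array in turn gave 14742 to 17018 called tiles for cbp1 deletion, 19594 to 25247 for clr3 deletion clr6-1 and 14809 to 18458 for the difference, the lone array left being assumed to vary like the other group. With the replicate number as a block 18165, 24235 and 17775 tiles were called. The numbers name 2 arrays per mutant and nothing says that they pair them, since deviations of equally numbered arrays correlated at 0.0750. Not run were the median of probes per gene, genes with at least 2 probes, and probes matching the genome more than once, which need a pairing with genes or a genome. Signal over background was lowest in the wild-type channel of the clr3 deletion clr6-1 arrays, where it limits ratios of dim tiles most.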

Other observations

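Of the tests below, those on family 2 and the one on the share of variance held by base counts were chosen after the results were seen. In clr3 deletion clr6-1 cells some long regions fell on 1 strand while the other rose. On chromosome 2 from 1481100 to 1488300, 13 tiles of the R strand fell 2.10-fold (mean log2 -1.07), while the 11 opposite tiles averaged 1.20 and none of them fell. On chromosome 3 from 1901700 to 1909500, 14 tiles had a mean of -0.73, against 0.79 on the opposite strand. In cbp1 deletion cells the same tiles averaged 0.09 and 0.39. A run of 22 tiles from 2815200 to 2828400 on chromosome 2 rose 2.03-fold on the R strand, with -0.17 on the opposite strand, and the wild-type channel was not well above background on 11 of its tiles. These regions were picked from the longest runs for this pattern after their values were seen. In other long runs of this mutant the opposite strand went the same way. Those were falls at 4308300 and 739800 on chromosome 1 (opposite strand -0.24 and -0.18). The rises were at 5550000 and 32100 on chromosome 1 (1.55 and 1.68) and on contig mito (0.65).

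Tile changes of the mutants went together, with a correlation of 0.265. Dye bias that follows the base composition of a probe might give such a correlation on arrays without a dye swap. The planned removal of the linear trend on base counts left the correlation at 0.268 but could hardly have moved it, and other forms of this bias stay open. A linear trend on base counts is argued against, since it held 0.471% and 0.552% of the variance of the mutants' means and can give at most 0.00510 of the correlation. A trend with brightness left by the normalization is argued against as the whole cause, since the mean correlation within 10 equal groups of wild-type brightness was 0.250 (0.137 to 0.413). Dye bias of single probes and a response that the mutants share stay open.

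Tiles of the dimmer strand rose more often than they fell in clr3 deletion clr6-1 cells. Copying of the brighter strand into second-strand cDNA, at an equal rate in both channels, could produce this only beside a rising brighter strand. Yet 76.8% of the 1854 dimmer-strand tiles up at least 2-fold with a measured neighbour had no opposite-strand neighbour that rose. That share counts measured neighbours only. Of brighter-strand tiles 9012 of 15216 were measured in this mutant, so rising neighbours may have been missed. Copying at an equal rate is therefore argued against less firmly. More copying in the mutant's labelling than in the wild type's could raise these ratios beside an unchanged brighter strand. No dye was swapped, so this unequal copying cannot be decided and stays open. Background correction of dim spots stays open, because among 9477 tiles above background in both channels on all arrays the median was 0.0293, against 0.0822 over the tiles compared. That value lies between what was predicted with and without this cause, and without background correction the median was 0.04 (adjusted p = 0.0166 with the preset correlation). An effect of the deacetylase mutations is a hypothesis that these arrays cannot separate from that correction or from unequal copying.

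Family 2 rose in cbp1 deletion cells. A dye bias shared by both mutants may raise a family on every array, but it would cancel in the difference between the mutants, which was 2.56 (SE 0.129) on the brighter strand over 10 tiles. On the dimmer strand the difference was 0.217 (SE 0.116), called as a fitted mean under 3 other settings and as a class under 5, so this bias stays open there. Copying of the rising brighter strand into second-strand cDNA was not tested for the dimmer strand and stays open as well. Temperature, slide and scan were shared by both channels of an array and bear on these differences rather than on the rise over wild type, for which a dye bias particular to 1 slide and an effect of losing Cbp1 stay open. Which copies of the family rose cannot be read from probes that share sequence.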
